A study of Oryzias latipes with 12 samples.

How the data were processed

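Gene expression was measured in whole brains of adult male medaka (Oryzias latipes, a small freshwater teleost that breeds in the long, warm days of the year). The fish came from a dealer and were held outdoors. Per the labels, 6 fish stayed in short-day, cool conditions (SC, 10 h of light and 14 h of dark) and 6 fish were moved from SC to long-day, warm conditions (LW, 14 h of light and 10 h of dark at 26 °C). Brains were taken 2 weeks after the move, around the middle of the lit hours. The labels give no temperature for SC. RNA of each fish was prepared and hybridised on its own, so each array is a separate animal and a group has 6 biological replicates.

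The arrays were one-colour (Cy3) Agilent arrays of a custom design, labelled with the Low Input Quick Amp kit per the labels. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, which subtracted the background and removed spatial trends, and no normalization between arrays was applied. Per the file headers, the other deposited columns hold flags of each spot (outlier, well above background, saturated, control). The authors also deposited a value table, on a log2 scale that the table itself does not state. Set against the scanner values of the same array, its columns had a slope of 0.997 to 1.00 and a Pearson correlation of 0.999 to 1.00 across probes with log2 signal minus the array's 75th percentile, centred on each probe's median over the 12 arrays. Scale, centring and direction of that table were found in this way, and its column medians ran from -0.01 to 0.01. The steps by which the authors made it are not given in the sources used here. It served as an alternative.

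From the scanner files, log2 of the processed signal minus the array's 75th percentile of it (0.75) was taken, with control spots left out and spots marked as non-uniform or population outliers set to missing (1 to 10 such spots per array). The array holds 43803 spots of 31090 probes for 27793 targets. Of the probes, 18377 were spotted once and 12713 were spotted 2 times, and spots of a probe were averaged. A probe was tested where it was well above background on at least 6 of the 12 arrays and had at least 4 unmarked values per group. This left 26413 probes (85.0%) and left out 4677. Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probes. A probe is called changed at an adjusted p under 0.05. Levels are log2 values relative to the array's 75th percentile, and a difference is LW minus SC. For arrays, the number of fish limits the precision.

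Single values per array were compared with an exact permutation test over all regroupings of the 12 arrays, two-sided. With 6 against 6, the smallest p such a test can give is 0.00216. Where a probe was not well above background on any array of a group, the difference is given as a bound: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value well above background. The arrays lay on 3 slides. Slide 1 held SC 1 to SC 4, slide 2 held SC 5, SC 6, LW 1 and LW 2, and slide 3 held LW 3 to LW 6. Each slide was scanned as 1 unit, so slide and scan are the same batch. Slide was fitted as a block, as a random block and within slide 2.

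The rule for named genes, fixed before the data were examined, took the 10 largest increases and the 10 largest decreases with an adjusted p under 0.05, an informative symbol and groups that did not overlap, plus members of 35 gene lists and a fixed set of thyroid, clock and stress genes as values. The files pair almost no target ID with a gene. Of 19 probes named by an accession or a gene, 1 has a gene name in the files (TSHB2) and 1 accession had a symbol in the RefSeq table of assembly ASM223467v1. The 1498 entries of the 35 lists matched 0 probes, so no list and no cell type marker was tested, and counts of named genes were not made. The same ranking was therefore applied to target IDs and held to 2 that rose and 2 that fell. This limit, the grouping of probes by ID prefix, the use of the 19 accession or gene-named probes and the sets of co-varying probes were chosen after the data were seen. Every probe is listed as unmapped in the files, so no coordinates are given.

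Sets of co-varying probes were made from probes well above background on at least 3 arrays with a standard deviation over 1.5 within groups. They were joined by average linkage on 1 minus Pearson's r of deviations from the group means over the 12 arrays, at a height of 0.3, and sets of at least 20 probes were kept. The 4 printed probes were compared with all other probes with BLAST 2.17.0, counting those with at least 30 identical bases. Prefix groups were compared with all other probes by Fisher's exact test, two-sided, and for the share changed also by a test stratified by deciles of mean level. The 11 groups were adjusted together by Benjamini-Hochberg. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

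The main fit was checked on simulated data for the 26413 probes of LW against SC, in which 200 probes were changed. It recovered 24% of 50 probes changed by 0.5 on the log2 scale, 74% of 50 changed by 1, 90% of 50 changed by 2 and 94% of 50 changed by 3. Of its 147 calls, 6 were false. The simulated noise was independent between probes and held no slide effect. The 200 changed probes were also far fewer than the 9368 called in the data. These rates therefore need not hold for the data. Alternatives covered background correction (normexp with an offset of 50, then quantile normalization), quantile and median scaling, the authors' value table, the filter on dim probes, marked spots, slide, a replicate block, the variance model, array weights and each fish left out. Scaling to the spike-in probes, slide 2 alone, slides 1 and 3 alone, a correction for GC content in 20 bins, normexp with no offset, sets made from deviations in place of levels and a count without the co-varying sets were added after the data were seen.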

Results

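Transcript levels were measured in the whole brains of 12 adult male medaka, 6 kept in short-day, cool conditions (SC) and 6 sampled 2 weeks after a move to long-day, warm conditions (LW). The comparison asks which brain transcripts differ between fish in winter-like and fish in summer-like conditions. Day length and temperature changed together, so the comparison is of both at once. Probes well above background made up 81.8% to 85.0% of all probes on the SC arrays and 82.9% to 86.0% on the LW arrays. Across probes, levels of fish of the same group correlated with a median Pearson's r of 0.964 and levels of fish of different groups with a median of 0.942. The first principal component held 32.9% of the variance over 26401 probes and the second held 18.0%. On the first, all 6 SC fish lay on one side of all 6 LW fish. On the second, the 4 arrays of slide 2, which held both groups, had the 4 lowest of the 12 scores (-79.24 to -21.58).

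Transcripts that differed between LW and SC were many, in nearly equal numbers up and down, and most differed by small amounts. Of 26413 probes tested, 9368 (35.5%) changed, 4879 of them higher and 4489 lower in LW (limma, two-sided, adjusted p under 0.05). The median size of a change was 0.60 on the log2 scale (1.52-fold), against a median standard deviation between fish of 0.24 in SC and 0.25 in LW. Among the changed probes, 7386 (78.8%) differed by less than 2-fold, and 1982 by 2-fold or more, 1037 of them higher and 945 lower. After normexp background correction and quantile normalization 801 probes changed by 2-fold or more, and 1127 with no offset added. Changed probes belonged to 8737 of the 23980 targets tested.

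The largest changes went mostly downward. At least 8-fold differences were found for 120 probes, of which 98 were lower and 22 higher in LW. These counts were made in the main fit alone, and some of the probes varied together between fish of a group, as described below. Some probes were well above background in 1 group alone. These were 39 probes on all 6 LW arrays and on no SC array, and 29 probes on all 6 SC arrays and on no LW array. All of these changed, which the way they were picked makes likely in advance. By the bound that the background allows, the 39 were at least 1.92-fold higher in LW at their median and the 29 at least 3.49-fold lower. In 5032 probes (19.1%) the values of the 6 LW fish all lay on one side of those of the 6 SC fish, where chance gives 0.216%.

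**Figure D1:**
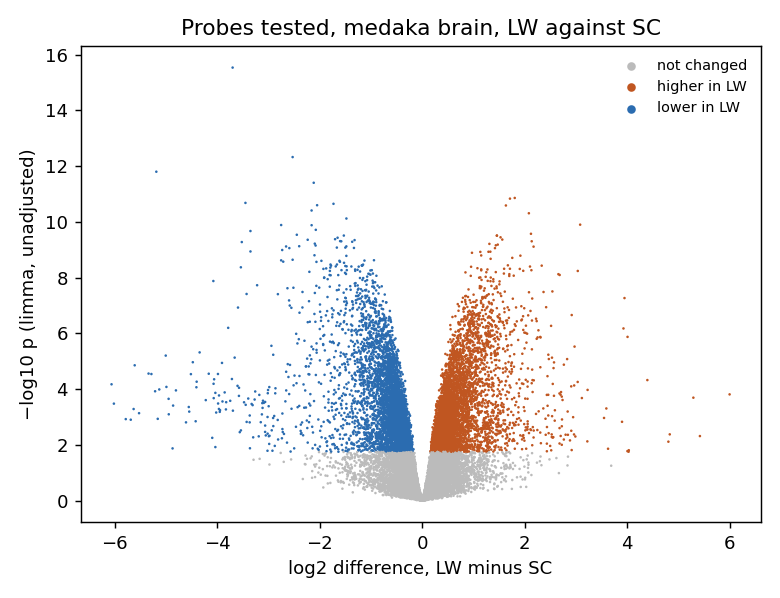
Log2 difference, LW minus SC (horizontal axis), against −log10 of the unadjusted limma p (vertical axis) for the 26413 probes tested, one point per probe, coloured by whether it was higher in LW (4879), lower in LW (4489) or not changed. Most changed probes lie within 2-fold, and the far left, beyond 8-fold, holds more probes (98) than the far right (22).

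The count of changed probes depended on how the slides were treated. With slide as a block, where the estimate rests on the slide that held both groups, 3220 probes changed (1579 higher, 1641 lower). Within that slide alone, with 2 fish per group, limma called 1 probe, and 6931 had an unadjusted p under 0.05. The direction split depended on the scaling. The split of 52.1% higher is relative to the array's 75th percentile. It was 50.4% under quantile normalization and in the authors' value table, 50.3% after normexp and quantile normalization, 49.0% with slide as a block and 49.6% with the trend with GC content removed, so no majority of either direction is read from it. By contrast, scaling to the spike-in probes called 12241 probes, of which 12.8% were higher and 10678 were lower. Spike-in scaling moved the median difference of all probes by -0.36. The directions reported here are relative to the 75th percentile and do not include that shift.

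Among transcripts whose 2 groups did not overlap, the targets olec20o08 and olova30f17 had the largest increases in LW. The files give no gene for either. The probe of olec20o08 (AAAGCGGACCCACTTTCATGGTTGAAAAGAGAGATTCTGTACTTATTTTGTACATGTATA) had a level of -4.26 ± 0.78 (SD, n = 6) in SC and 1.74 ± 2.83 (SD, n = 6) in LW, a log2 difference of 6.00 (SE 1.1, limma adjusted p = 0.00135). Its level differed widely among LW fish, from -2.49 to 4.68. Another probe of the same target gave a difference of 5.29. The probe of olova30f17 (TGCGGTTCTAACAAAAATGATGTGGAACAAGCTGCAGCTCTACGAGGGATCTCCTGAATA) rose from -4.93 ± 1.43 to -0.54 ± 1.23 (SD, n = 6 each), a difference of 4.40 (SE 0.71, limma adjusted p = 0.000566). It was well above background on 4 of the 6 SC arrays and on all 6 LW arrays. Within slide 2 the differences were 7.91 and 4.73, with a sign fixed in advance by the choice of groups that did not overlap. After normexp background correction and quantile normalization the differences were 4.50 and 2.38.

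The targets dola:20412 and dola:24889 had the largest decreases by the same rule, and the files name no gene for these either. The probe of dola:20412 (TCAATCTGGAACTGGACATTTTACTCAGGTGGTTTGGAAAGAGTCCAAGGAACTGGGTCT) went from 1.78 ± 1.22 in SC to -4.28 ± 2.41 in LW (SD, n = 6 each), a difference of -6.06 (SE 1.01, limma adjusted p = 0.000726). The probe of dola:24889 (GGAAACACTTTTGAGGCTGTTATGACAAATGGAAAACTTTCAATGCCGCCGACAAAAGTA) went from 4.75 ± 1.58 to -1.26 ± 2.81 (SD, n = 6 each), a difference of -6.01 (SE 1.21, limma adjusted p = 0.00238). Both were well above background on all 6 SC arrays and on 5 of the 6 LW arrays. A second probe of dola:24889 gave -4.55. The probe of dola:24889 shares 30 identical bases with 1 other probe on the array. With slide as a block the differences were -3.67 and -4.38, and neither passed the threshold. After normexp background correction and quantile normalization they were -4.11 and -5.17.

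**Figure D2:**
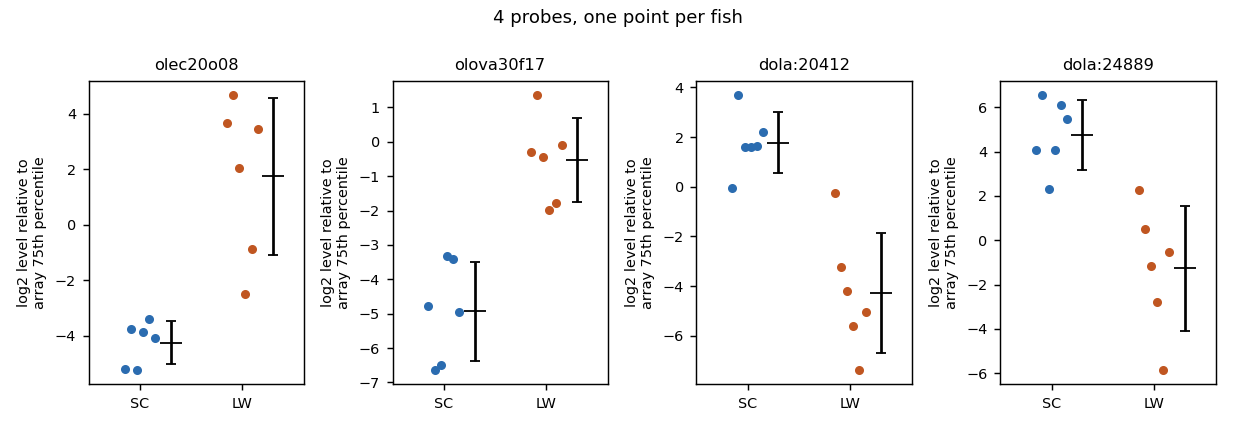
Levels of 4 probes, one panel each, in log2 units relative to the array's 75th percentile; each point is a fish, and the bar beside each group is its mean ± SD (n = 6 per group). The panels for olec20o08 and olova30f17 show all 6 LW fish above all 6 SC fish, and the panels for dola:20412 and dola:24889 show all 6 LW fish below.

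Some transcripts varied together between fish of the same group. Among 717 probes with a wide spread within the groups, joined on deviations from the group means so that the difference between LW and SC took no part, 3 sets of at least 20 probes followed a shared course over the fish. Set 1 (174 probes of 160 targets) holds olec20o08, which rose, and dola:20412 and dola:24889, which fell. Of its 172 tested probes 34 changed, 9 higher and 25 lower, among them 7 of the 22 probes higher and 19 of the 98 lower by 8-fold or more. Its median level was -1.75 ± 1.11 in SC and -2.89 ± 2.09 in LW (SD, n = 6 each; exact permutation p = 0.290, two-sided, adjusted over the 3 sets 0.870). In sets 2 and 3, 0 of 99 and 0 of 14 tested probes changed by limma. Probes of a set were picked for a wide, shared spread, so they are harder to call and tend to be missed together. These counts therefore do not show that the sets were the same in LW and SC. Within slide 2 the differences of the set medians were -0.13, 0.80 and -0.34.

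**Figure D3:**
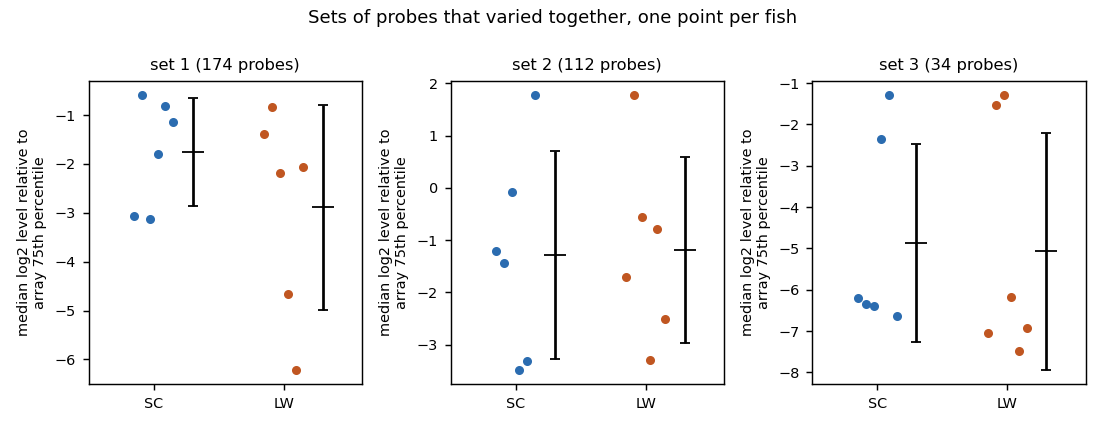
Median level of each of 3 sets of co-varying probes in each fish, in log2 units relative to the array's 75th percentile (each panel has its own scale); points are fish, bars are mean ± SD (n = 6 per group). In all 3 sets the fish of both groups overlap.

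The groups of target IDs on the array differed in direction, although the files do not say what the prefixes stand for. Changed probes of the prefixes OLA (352 of 462, 76.2%), olbr (430 of 619, 69.5%), oleb (220 of 327, 67.3%) and olec (193 of 316, 61.1%) were higher in LW more often than the other changed probes (Fisher's exact test, two-sided, adjusted p = 5.83e-27, 4.18e-19, 5.30e-08 and 0.00287). Changed probes of the prefix dola, the largest group, were higher in LW less often, at 47.3% of 6382 against 62.4% of the others (adjusted p = 1.03e-41). The same held for Ensembl medaka transcripts (ENSORLT), at 43.1% of 255 (adjusted p = 0.00765), a share that was 34.1% of 220 under quantile normalization and 6.58% of 76 with slide as a block. Spike-in scaling moves the differences of all probes by the same amount, so it cannot test how a prefix leaned relative to the others. Under it most changed probes of every prefix were lower. Of the changed OLA probes 20.8% were higher against 12.4% of the others, and of the dola probes 10.6% against 17.9%. Ensembl transcripts also changed more often than other probes, 45.9% against 35.2% (adjusted p = 3.22e-06, and 2.46e-07 when stratified by level), although with slide as a block the shares were 13.7% and 12.2% (Fisher's exact test, unadjusted p = 0.265). Changed probes were rarer among olova targets, 30.2% against 35.6% (adjusted p = 0.0102, and 0.0241 stratified), with shares of 10.4% and 12.2% under the slide block (unadjusted p = 0.129) and of 44.1% and 46.4% under spike-in scaling (unadjusted p = 0.210). Among OLA targets 33.2% changed against 35.6% (adjusted p = 0.144, and 0.00413 stratified), with unadjusted p = 0.00289 under quantile normalization, 0.00545 with slide as a block and 3.71e-15 under spike-in scaling, where the shares were 36.2% and 46.9%. The downward shift of spike-in scaling brings probes that lean upward, as OLA probes did, nearer to no difference. The share of OLA probes changed under it is therefore no separate support. These tests take probes as independent, and probes are not independent replicates. The tests of direction were not stratified by level and were not repeated with the GC trend removed. Over all tested probes the difference was weakly lower at higher GC content (Spearman's rho -0.10), so a part due to GC content or level was not tested.

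**Figure D4:**
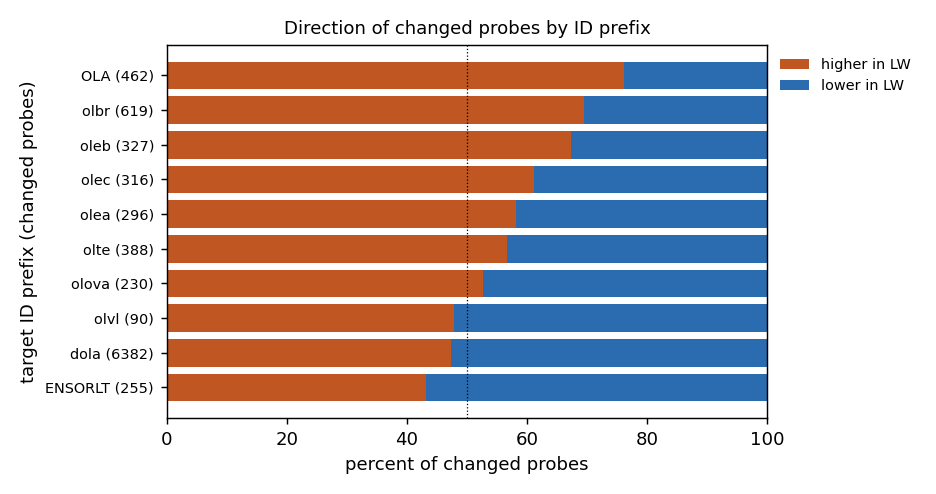
Percent of changed probes that were higher (orange) or lower (blue) in LW, by the prefix of the target ID, with the number of changed probes in parentheses and a dotted line at 50%. Levels are relative to the array's 75th percentile, and under spike-in scaling most changed probes of every prefix were lower. The highest share of higher probes was in OLA (76.2%) and the lowest in ENSORLT (43.1%).

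Only TSHB2, named for a beta subunit of thyroid-stimulating hormone, has a gene name in the files. It was well above background on 3 SC and 2 LW arrays, too few to be tested, with levels of -5.56 ± 1.33 in SC and -6.30 ± 1.54 in LW (SD, n = 6 each; difference -0.74, exact permutation p = 0.379, two-sided). On slide 2 it was well above background on both SC arrays and on neither LW array, with a difference of -2.53. The other slides did not show this fall: there it was well above background on SC 2, LW 3 and LW 6. Levels on them overlapped, from -6.95 to -4.66 in SC and from -8.32 to -4.09 in LW. Both differences of TSHB2 include values that were not well above background, so their sizes are not exact. LOC101158465, named through its RefSeq accession, was well above background on 2 SC arrays and 0 LW arrays, and its bound is under 1-fold, so no fold is given. Of the 19 probes named by an accession or gene, 11 were tested and 3 changed, and their names are given after their values were seen. JX293358 rose by 0.69 (limma adjusted p = 0.0181) and XM_004080364 by 0.53 (limma adjusted p = 0.0468), and NW_004089744 fell by 0.59 (limma adjusted p = 0.0306). The exact permutation test, adjusted over the 19 probes, gave p = 0.103, 0.140 and 0.123 for these differences, so none passed by it. Within slide 2 these differences were 0.73, 0.72 and -0.66. None of the 3 was called with slide as a block, and both rises were lost under spike-in scaling (0.33 and 0.17). Over 29 alternative settings all 3 kept their sign, and the call was lost in 4 settings for JX293358, in 22 for XM_004080364 and in 11 for NW_004089744, with 0, 9 and 7 of these among the 12 in which a single fish was left out.

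Probes of one target mostly moved together. On the array 467 probes share the sequence of another probe. Such probes were not left out here, so the agreement may include pairs of identical sequence. For 2433 targets with 2 tested probes, the log2 differences of the probes correlated across targets with a Pearson's r of 0.798. Both probes changed for 631 targets, where 302 would be expected if they were independent, and 624 of these (98.9%) went the same way. In 453 targets 1 of the probes changed, and in 1349 neither. By signal, 27.1% of the dimmest 5283 tested probes changed, 36.8% of the middle 5283 and 42.3% of the brightest 5283. Changes of 2-fold or more were called for 559 of the dimmest and 267 of the brightest. For 10723 tested probes spotted 2 times, the median standard deviation was 0.07 between the spots of an array and 0.25 between fish of a group, which includes labelling and hybridisation.

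The LW arrays were dimmer than the SC arrays before scaling. The 75th percentile of the signal was 797 ± 28.4 in SC and 669 ± 47.1 in LW (SD, n = 6 each), a log2 difference of -0.25 (exact permutation p = 0.00216, two-sided, the smallest this design allows; adjusted over 6 measures 0.00325). The spike-in probes went the other way, by 0.10 (exact permutation p = 0.0152, adjusted 0.0182). The summed signal of all spots differed by -0.16 (exact permutation p = 0.00216, adjusted 0.00325), and the brightest 1% of spots held 58.1% of the signal in LW against 55.7% in SC (exact permutation p = 0.00216, adjusted 0.00325). The share of probes well above background was 84.9% in LW and 83.5% in SC (exact permutation p = 0.0649, adjusted 0.0649). Within slide 2 the differences were -0.30 for the 75th percentile, 0.12 for the spike-ins and -0.15 for the summed signal.

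**Figure D5:**
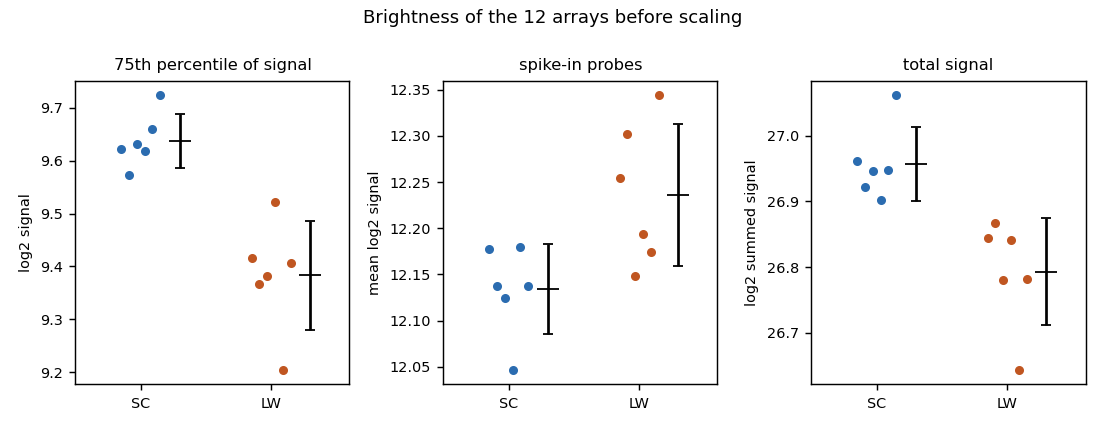
Log2 of the 75th percentile of signal, mean log2 signal of the spike-in probes and log2 of the summed signal on each array before scaling; points are arrays (1 fish each), bars are mean ± SD (n = 6 per group). The 75th percentile and the summed signal lie lower in all 6 LW arrays than in all 6 SC arrays, and the spike-ins lie higher in LW on average, with overlap.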

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

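The tests of slide, GC content, spike-ins and total signal described here were chosen after the data were seen.

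The number of probes that changed between LW and SC, 9368, was set against explanations other than the conditions. Of 100 splits of the 12 arrays into 2 groups of 6, drawn from 462, only 1, the real one, gave as many. The highest of the others gave 4. This argues against a chance division of the fish, at 1 in 100, the smallest share these splits allow. The other splits mix LW and SC, which adds to the spread within their groups, so the 4 does not measure how unlikely chance is. Of the 6250 probes called from slides 1 and 3 alone, 96.1% had the same sign between the groups on slide 2, which argues against slide as the whole cause, although the second principal component set slide 2 apart and a part due to slide stays open. With each array's trend with probe GC content removed, 9439 probes changed, which argues against GC content. The move to LW is a candidate explanation, as a hypothesis only, and the design does not separate day length from temperature, nor either from handling at transfer.

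The 75th percentile of signal was lower in LW by a log2 difference of -0.25. If the arrays had simply been dimmer the spike-ins would have been lower too, and they were higher by 0.10, which argues against array brightness. If signal had only moved to the brightest probes the total would have stayed level, and it differed by -0.16, although the brightest 1% of spots held a larger share in LW. A smaller amount of labelled messenger RNA per unit of total RNA in LW brains is a possible explanation that was not tested, and so are RNA quality and the amount of RNA labelled. Which of the scalings gives the right direction for a probe of small difference therefore stays open.

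A check for a single outlying fish was made in 40 groups of 6 values, of which chance picks out about 1 in 20, and it picked out 2. The log2 summed signal of SC 6 was 27.06 against 26.96 for the nearest SC array. AB223057, a probe outside the main test, had a level of -6.48 in SC 4 against -7.56 in the nearest SC fish, although it was well above background on no SC array.

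Among the probes left out of the main test because they were dim, 137 were well above background on at least 4 LW arrays and no SC array, and 44 on at least 4 SC arrays and no LW array. AB223057, named after its values were seen, is one of the former: it was well above background on 4 LW arrays and at least 1.34-fold higher in LW (all 6 LW fish above all 6 SC fish, exact permutation p = 0.00216, 0.0411 after adjustment over the 19 accession or gene-named probes).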

How the results depend on the processing

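Spike-in scaling, slide 2 alone, slides 1 and 3 alone, the GC correction, normexp with no offset, sets made from deviations in place of levels and the count without co-varying sets were chosen after the data were seen. Under quantile and median scaling, the authors' value table, either filter on dim probes, marked spots kept, slide as a random block, the trended and robust variance models and array weights, 8688 to 9934 probes changed, against 9368. With each fish left out the count ran from 8280 to 9261, the 2-fold count from 1884 to 2011, the higher probes from 4234 to 4879 and the lower from 4028 to 4562. With slide as a block 3220 probes changed (1579 higher, 1641 lower), of which 3023 were also called without it. By construction that estimate rests on the 4 arrays of slide 2, and its standard error was 1.71 times as large at the median. On slide 2 alone 1 probe was called, it was higher and at least 2-fold (1 higher, 0 lower), with 2 fish per group. Slides 1 and 3 alone gave 6250. The GC correction gave 9439, and 9334 changed probes were outside the co-varying sets. After normexp and quantile normalization 801 probes changed by 2-fold or more, against 1982, 1127 with no offset in place of 50, and 1990 with quantile normalization alone, so most of the fall came with normexp background correction and its offset. Spike-in scaling called 1563 probes higher and 10678 lower, since it moves all differences by -0.36 by construction. The 4 printed targets kept their direction under every setting in which they had a value, with their smallest sizes at 4.50 (olec20o08) and 2.38 (olova30f17) under normexp with the offset. They were picked for groups that did not overlap. With a fish left out, on part of the slides or with slide as a block, their direction was therefore fixed in advance and is no test. Under the slide block dola:20412 (-3.67) and dola:24889 (-4.38) no longer passed, and on slide 2 alone none of the 4 passed.

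Sets were first made from levels, which gave 5 in place of 3. Of the 24 probes of 1 of these, all 23 tested were lower in LW, but the difference between the groups took part in that grouping, and 21 of the 24 lay in set 1 when it did not. Of another 23 probes, 18 of 21 tested were lower, 16 of them by 8-fold or more, with a difference of -3.55 between the group means of their median level and of -4.04 within slide 2. None of these 23 lay in sets 1 to 3, and since the grouping used the difference, no test of it is given.

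The replicate numbers in the labels were not used as pairs, since each number names a separate fish. Same-numbered fish had deviations from their group means that correlated at -0.228 to 0.147 across probes, 2 of 6 pairs were over 0.1, and 2 fish correlated best with their own number. With the replicate block 7788 probes changed. Counts of named genes, gene list tests, the choice of probe per gene, the estimated correlation and fry were not run, since the lists matched 0 probes. Signal over background limits the dim probes, of which 4677 were left out.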

Other observations

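All tests of the sets of co-varying probes described here were chosen after the sets were seen.

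Groups of transcripts in the whole-brain samples, of brain or of other tissue taken along, differed widely between fish of the same group. Set 2 (112 probes of 104 targets) ran over a range of 5.27 on the log2 scale (38.6-fold) among the 12 fish, while its group means were -1.29 ± 1.99 in SC and -1.18 ± 1.78 in LW (SD, n = 6 each; exact permutation p = 0.920, two-sided, adjusted over the 3 sets 0.920). Set 1 ran over 5.63 (49.7-fold), from -6.22 in LW 5 to -0.59 in SC 2, and its medians on the 4 arrays of slide 2 lay between -1.38 and -0.82. Set 3 (34 probes of 34 targets, among them AB223053, AB223054 and AB223055, named after their values were seen) had medians of -2.36 in SC 4, -1.28 in SC 5, -1.53 in LW 2 and -1.29 in LW 3, and of -6.18 or lower in each of the other fish. Its group means differed by -0.20 (exact permutation p = 0.764, adjusted 0.920). TSHB2 and LOC101158465 were not well above background at any level of -5.53 or lower. The median of set 1 in LW 5 and those of set 3 at -6.18 or lower thus lie near background. The fold range of set 1 and the difference of set 3 are therefore not exact. The probes were picked because they varied between fish, so their spread is large by choice.

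What makes these probes vary together was tested in part. For 138 of their 320 probes, those spotted 2 times, the spots of a probe followed each other over the arrays with a median Pearson's r of 0.997 and differed by a median of 0.09 on the log2 scale, which argues against spot defects. In each of the 3 sets a single slide held at least 0.739 of the set's whole range, which argues against slide as the whole cause. RNA of other cells or tissue taken along with the brain is a possible explanation that stays open. The marker lists were matched by symbol, and 0 entries matched a probe. Probes known by an accession alone, such as those named in set 3, could not be matched. Differences in physiological state between fish are also possible and were not tested.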
